A study of Drosophila melanogaster with 8 samples.

How the data were processed

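Gene expression was measured by RNA-seq in cuticle with attached fat body from 1-week-old adult Drosophila melanogaster females. Per the labels' protocols, total RNA was extracted, polyadenylated RNA was selected, fragmented and reverse transcribed, and the amplified libraries were sequenced on an Illumina instrument. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 were used with the genome build BDGP6. The order of these steps, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Each deposited file held raw read counts per gene for 1 library, per the file headers in the layout that featureCounts writes, and carried no normalization.

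All 8 files held the same 17411 genes, and every count was a whole number. Totals ranged from 25396063 to 36181492 counts per library. The common biological coefficient of variation was 0.500, so the spread between libraries, not counting error, set the precision for all but the scarcest genes. The symbols in the files are older FlyBase symbols. A later annotation and gene name tables were used for names only, and 17226 of the 17411 symbols were matched to a FlyBase identifier. Coordinates are those of the deposited files on BDGP6. Where a gene has a newer symbol, it is given in parentheses.

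Libraries were grouped by the genotype in the labels, as 4 controls and 4 9G8 RNAi libraries. The labels do not say whether the libraries of a genotype came from separately reared flies, so p-values measure the spread between these libraries. The replicate numbers are shared between the genotypes, and no label says that a number marks a shared day or batch.

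Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 9846 genes. Libraries were scaled by TMM factors, and the quasi-likelihood F test (glmQLFit, glmQLFTest) compared 9G8 RNAi with control without covariates. P-values were adjusted by the Benjamini-Hochberg method, and a gene was taken as changed at an adjusted p under 0.05. The unit of the levels is CPM, computed here from the deposited counts with TMM factors, and given as mean ± SD over the libraries of a group. Log2 fold changes are 9G8 RNAi over control, with a standard error (SE) derived from the F statistic. For 9G8 and the NADPH-producing enzymes, an exact two-sided permutation test of log2 CPM (prior count of 2) ran over all 70 assignments of 4 against 4 libraries. Its smallest possible p is 0.0286.

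Before the data were examined, 43 gene lists for pathways, fat body and other cell types, and the rule for naming genes, were fixed. Lists with at least 3 tested genes, 41 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 41 lists. Named genes were 9G8 itself, the 10 largest rises and the 10 largest falls among changed genes, the tested NADPH-producing enzymes, members of each list, and the 5 most abundant changed genes in each direction. The largest changes needed a mean CPM of at least 5 and groups that did not overlap. From a list, up to 4 members with the smallest adjusted p were named if any passed, and otherwise up to 2 with the highest mean CPM. Genes outside this rule are said to be chosen after their values were seen. Marker scores are the mean log2 CPM of a list in a library. Calls per chromosome arm were compared by Fisher's exact test.

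The count test and the list test were tested on simulated data made from the means, spread and library sizes of the real libraries, in 5 sets of 9846 genes with 200 changed genes each. For 9G8 RNAi against control, 2.35% of 2-fold changes, 34.0% of 4-fold changes and 95.4% of 16-fold changes were called, and 4.10% of calls were unchanged genes. A shifted list was called in 5 of 5 sets, and 0 of 100 unchanged lists were called. Each gene was drawn independently of the others, so the simulation does not show how camera treats lists whose genes vary together.

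Alternatives chosen before the data were examined were RLE size factors, TMM without the 20 most abundant genes, DESeq2 1.42.0, limma-voom, no low-count filter, a mean CPM of at least 1, the replicate number as a block, and each library left out in turn. For lists they were an estimated correlation and fry. Added after the data were seen were fits with a germline, an eggshell or a gut score as covariate and fits without 2 doubted libraries. Splicing, the target process of an SR protein, was not analysed here because the files hold gene totals. GC content was not checked, since no genome sequence was used here.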

Results

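RNA was profiled in the fat body of adult Drosophila females, taken as cuticle with the fat body attached. The fat body is the fly's main organ of fat storage, intermediary metabolism and humoral immunity. Flies carried yolk-Gal4, a driver active in the fat body of adult females. In the 9G8 RNAi group (n = 4) it expressed a hairpin against 9G8, an SR protein (serine- and arginine-rich splicing factor) encoded by the gene x16. Controls (n = 4) carried yolk-Gal4 over the w1118 chromosome, without a hairpin. Flies were 1 week old. Control libraries held 27946556 to 34750635 counts and 9G8 RNAi libraries 25396063 to 36181492 counts. Values are mean ± SD over the 4 libraries of a genotype. The share of counts in mitochondrially encoded genes was 12.5% ± 1.03 in controls and 16.2% ± 2.34 in 9G8 RNAi (exact two-sided permutation test, p = 0.0571, adjusted p = 0.343 over 6 quality measures). No 2 libraries held identical counts, and Spearman correlations within a group ran from 0.934 to 0.959.

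The comparison asks which fat body transcripts differ when 9G8 is targeted. Controls carried no hairpin transgene, so its insertion and any difference of strain background go with genotype. For no gene below can these be told apart from an effect of the hairpin. The level of the target comes first. The gene x16 (FBgn0028554) lies on the minus strand of 2L from 6914301 to 6920210. Its transcript was at 149.2 ± 123.8 CPM in controls and 96.5 ± 74.1 CPM in 9G8 RNAi, a log2 fold change of -0.63 (SE 0.63, adjusted p = 0.862 by edgeR's quasi-likelihood test). The exact two-sided permutation test of log2 CPM gave p = 0.486 (n = 4 against 4). Controls 1 to 4 were at 60.4, 65.6, 325.5 and 145.1 CPM, and 9G8 RNAi libraries 1 to 4 at 198.6, 34.7, 103.1 and 49.5 CPM. A lower x16 level was therefore not detectable in these libraries, and left out one at a time they gave log2 fold changes from -1.20 to 0.10, the latter without control 3. The 3 libraries with most x16 also had the 3 highest germline scores: the germline and nurse cell score was -0.28, 1.14, 3.78 and 4.03 in controls 1 to 4, and 4.28, 3.02, 2.89 and 1.69 in 9G8 RNAi 1 to 4. The span of x16 overlaps those of nop5, CG32829 and snoRNA:nop5-x16-a on the same strand, and reads of a hairpin copied from x16 would count towards x16. Of the other SR proteins and related splicing factors none changed (16 tested). Rsf1 was at 265.8 ± 96.1 CPM in controls and 129.9 ± 49.5 CPM in 9G8 RNAi (log2 fold change -1.03, SE 0.40, adjusted p = 0.261), with the groups apart. U2af50 had a log2 fold change of 0.13 (SE 0.34, adjusted p = 0.961). Of 11 sex determination genes none changed, and tra2, the SR-like splicing regulator of doublesex, was at 98.0 ± 32.9 and 37.8 ± 18.7 CPM (log2 fold change -1.38, SE 0.40, adjusted p = 0.0970). Without 9G8 RNAi 4, tra2 passed (log2 fold change -1.78, adjusted p = 0.0180). By camera, neither list stood apart from other genes (adjusted p = 0.292 and 0.673).

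**Figure D1:**
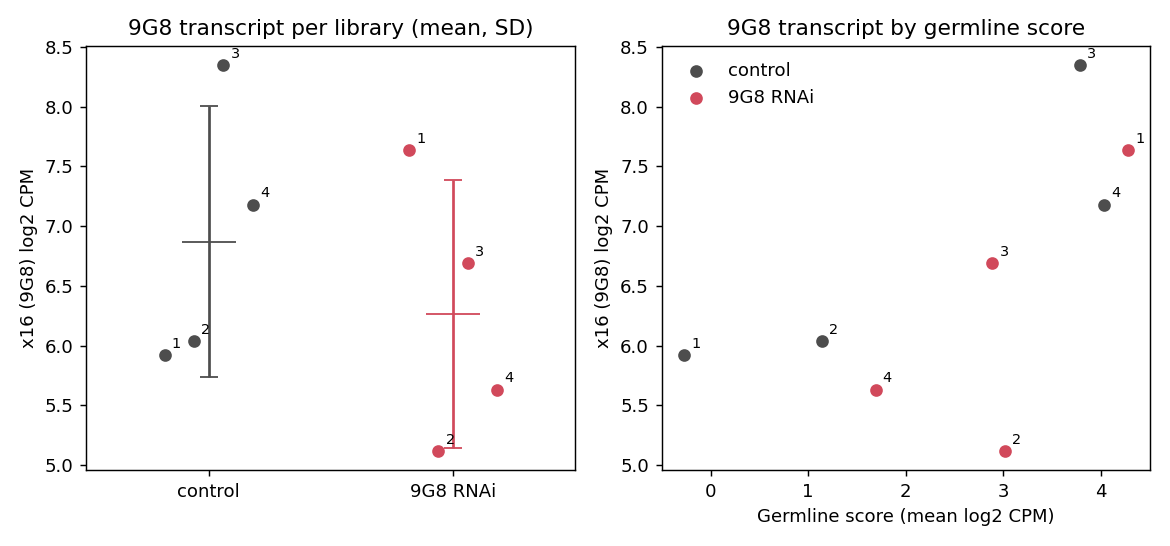
Level of the 9G8 transcript (x16, log2 CPM) in each library. Left, by genotype, with the mean and SD (n = 4); right, against the germline score, the mean log2 CPM of 20 germline and nurse cell genes. Numbers mark replicates; the groups overlap, with means of 6.87 in controls and 6.27 in 9G8 RNAi.

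Across the 9846 tested genes, 316 changed in 9G8 RNAi, of which 98 were higher and 218 lower. Each of them changed by more than 2-fold, the smallest by 1.24 on the log2 scale. The count of genes changed by at least 2-fold is thus the same 316 genes. In simulated data 2.35% of 2-fold changes were called, so this size partly reflects what the test could call. At an unadjusted p under 0.05 there were 1267 genes. In 305 of the 316 the 4 values of one genotype lay above the 4 of the other. Over all tested genes this held for 8.74%, where chance gives 2.86%. The count depended on single libraries: it was 198 without control 1, 187 without control 2, 162 without 9G8 RNAi 2, 179 without 9G8 RNAi 3 and 504 without 9G8 RNAi 4. Higher genes numbered 61, 60, 51 and 57 without control 2, control 3, 9G8 RNAi 2 and 9G8 RNAi 3. Lower genes numbered 119, 126, 105, 111, 122 and 380 without control 1, control 2 and 9G8 RNAi 1, 2, 3 and 4. With each library left out in turn, 126 of the 316 genes passed every time, 38 higher and 88 lower, and 35 of the 61 named genes that passed were among those. With a score of gut markers as a covariate, 32 genes were higher, and 19 of the 61 named genes no longer passed, among them glob1 (adjusted p = 0.0618) and Arc1 (0.0898). In that fit 4 of the 11 lists were lost too, among them the gut list, whose own mean the covariate removes. Without control 3 and 9G8 RNAi 2 together, 96 genes changed and 29 of the 61 named genes no longer passed. With the replicate number as a block, 141 genes changed and 22 of the 61 named genes no longer passed. A block, a covariate or fewer libraries can lower the power, so a call lost in such a fit need not mean a smaller change. With the eggshell score as a covariate 12 of the 61 were lost, and without control 4 and 9G8 RNAi 1 together 14. Other scalings, filters and tools ended 0 to 7 named calls each. Of the 61, 24 passed in every setting run for them: Hsp70Bb, CG5999, CG13659, CG6908, CG31288, GstE1, Cyp12c1, Cyp12d1-d and Cyp6w1 among the rises, and Ser12, Cpr49Ac, Cpr49Aa, Fst, CR45140, CR45949, CG43291, Drsl2, Drsl5, Lip3, Socs36E, Diedel, Hsp23, Cyp28d1 and LysX among the falls. Cyp12d1-d, with 1 count over the controls and 129 over 9G8 RNAi, was too scarce for the setting with a mean CPM of at least 1. How reads with several matches were treated is not known, so its counts are uncertain if a close copy shares its reads. The strand setting of the counts is not known, so reads of genes with overlapping spans cannot be assigned with certainty. Among the genes named here, mag, CG17192, Fst, CR45140, CR45949, Zw, Pgd, Lip3, Acox57D-d, tobi, Lsp2, Socs36E, Hsp70Ab, GstE1, Cyp28d1, CG4302, w, He, deltaTry and Rootletin overlap genes on the opposite strand, x16 and pug genes on the same strand, and Nmdmc, tra2, PGRP-SD and Pxn genes on both.

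The 10 largest rises among genes with a mean CPM of at least 5 included a lipase, a chaperone, a UDP-glycosyltransferase and trypsins. Magro (mag, a lipase) rose from 0.0709 ± 0.0688 to 13.5 ± 18.6 CPM (log2 fold change 7.57, SE 1.17, adjusted p = 0.00445), with 1916 of its 2259 9G8 RNAi counts in 9G8 RNAi 2. Hsp70Bb, a copy of the inducible heat shock chaperone, rose from 1.38 ± 1.70 to 162.9 ± 77.3 CPM (6.87, SE 0.87, adjusted p = 0.00171). CG5999 (Ugt37A3), a UDP-glycosyltransferase, rose from 1.19 ± 0.56 to 129.7 ± 39.2 CPM (6.77, SE 0.51, adjusted p = 1.2e-04). CG4563 (6.46), CG13659 (5.58), CG6908 (4.83), CG17192 (4.82) and CG31288 (4.10) also rose, but without control 3 and 9G8 RNAi 2 together CG4563 (adjusted p = 0.0657) and CG17192 (0.0628) did not pass, nor did thetaTry (0.0910), lambdaTry (0.193), glob1 (0.0645), Arc1 (0.0657) or Rootletin (0.136). So did the trypsin genes thetaTry (5.75) and lambdaTry (4.73) of a cluster of close copies on 2R, where counting could split shared reads. The call of thetaTry ended without 9G8 RNAi 2 (adjusted p = 0.0533), and that of lambdaTry without control 2, 3 or 4 or 9G8 RNAi 2 (adjusted p up to 0.0978). With the gut score as a covariate, mag (adjusted p = 0.117), lambdaTry (0.190) and Rootletin (0.149) no longer passed, and with the replicate block glob1 (0.0796), Arc1 (0.106) and Rootletin (0.155) did not. Rootletin was also lost with RLE factors (0.0706) and a mean CPM of at least 1 (0.0521). Among abundant genes, GstE1, a glutathione transferase, rose from 71.5 ± 20.5 to 906.2 ± 288.6 CPM (3.67, SE 0.40, adjusted p = 9.5e-04). The hemoglobin gene glob1 (2.19, SE 0.39) and Arc1 (2.08, SE 0.38) rose about as far as each other, from 210.0 to 955.8 CPM and from 192.4 to 811.3 CPM. Rootletin, a component of ciliary rootlets, was at 149.4 ± 73.2 and 599.8 ± 169.9 CPM (2.01, adjusted p = 0.0456). Of the 8 fits that left a library out, its call was kept in 1, without control 4, and the adjusted p in the others was 0.0587 to 0.124.

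The 10 largest falls among such genes included cuticle, immune and noncoding genes. Ser12, a serine protease, fell from 14.5 ± 8.50 to 0.0359 ± 0.0242 CPM, with 1732 counts over the controls and 5 over the 9G8 RNAi libraries (log2 fold change -8.51, SE 0.78, adjusted p = 4.1e-04). The neighbouring cuticle protein genes Cpr49Ac and Cpr49Aa on 2R fell together (-6.54 and -6.17). Cpr49Aa went from 437.8 ± 98.5 to 6.12 ± 6.17 CPM. Frost (Fst), a gene known for its induction by cold, fell from 1873 ± 1047 to 30.6 ± 35.2 CPM (-5.94, SE 0.84, adjusted p = 0.00284). It overlaps Dh44 on the opposite strand, and with a library left out its log2 fold change ranged from -7.14 to -5.41. The noncoding RNAs CR45140 (-5.86), CR45949 (-5.48) and CR34262 (-4.60) fell, as did CG43291 (-5.72) and the drosomycin-like genes Drsl2 (-5.63) and Drsl5 (-5.10). CR45140 overlaps CG17574 on the opposite strand. CR34262 no longer passed without 9G8 RNAi 2 (adjusted p = 0.0613), nor without that library and control 3 together (0.105). Of 29 cuticle protein genes tested, 2 fell, 0 rose and 27 did not pass, with 3 lower when adjusted over the list alone (camera adjusted p = 0.0933, and 0.0358 without control 3 and 0.0363 without 9G8 RNAi 3).

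In the fixed list of enzymes that supply NADPH, the reducing power for fatty acid synthesis, 1 of 7 fell. Glucose-6-phosphate dehydrogenase (Zw, FBgn0004057, X from 19667252 to 19672353), which opens the pentose phosphate pathway, fell from 1384 ± 625.6 to 264.2 ± 189.3 CPM (log2 fold change -2.39, SE 0.54, adjusted p = 0.0337). The 4 control values, 691.1 to 2209 CPM, lay above the 4 of 9G8 RNAi, 105.8 to 538.6 CPM. The exact two-sided permutation test gave p = 0.0286, the smallest it can give, and 0.100 after adjustment over the 7 enzymes. The call was lost when control 1, 2 or 3 or 9G8 RNAi 1, 2 or 3 was left out (adjusted p = 0.123, 0.0784, 0.0574, 0.0993, 0.118 and 0.113) and with RLE factors (0.0545), the replicate block (0.141), the eggshell covariate (0.111) or without control 3 and 9G8 RNAi 2 together (0.202), while with a library left out the log2 fold change stayed between -3.01 and -1.97. The other 6 enzymes did not pass. Phosphogluconate dehydrogenase (Pgd) was at 1148 ± 343.1 and 625.0 ± 239.5 CPM (-0.88, SE 0.39, adjusted p = 0.371). Nmdmc, of one-carbon metabolism, was at 28.1 ± 3.42 and 15.7 ± 3.65 CPM (-0.84, SE 0.30, adjusted p = 0.195), with the groups apart. Nmdmc stands in this list although it is named as an NAD-dependent enzyme. The malic enzymes Men and Men-b had log2 fold changes of 0.12 and -0.05, Idh 0.64 and pug -0.60. The NADPH list (0 higher, 1 lower, also when adjusted over the list alone) and the pentose phosphate list (7 tested, 1 lower) did not pass camera (adjusted p = 0.152 and 0.0543). The pentose phosphate list passed without control 4 (0.00739), 9G8 RNAi 3 (0.0325) or 9G8 RNAi 4 (0.0237), at the preset correlation of 0.01. Its correlation estimated over all libraries was 0.602, and camera with that value gave adjusted p = 0.924.

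**Figure D2:**
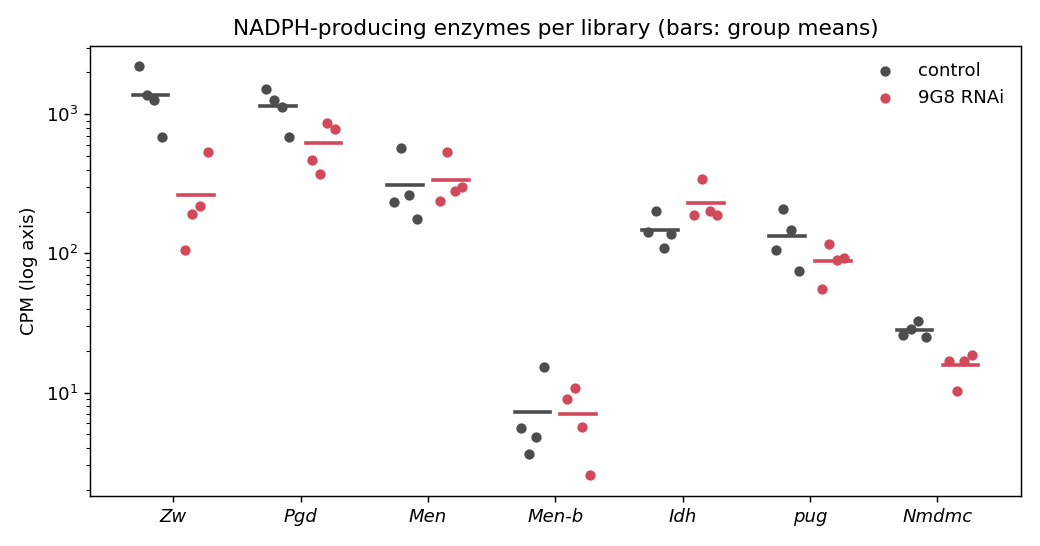
CPM of the 7 genes in the fixed list of NADPH-producing enzymes, in each library, on a log axis. Points are libraries (n = 4 per genotype) and bars are group means; for Zw the 4 controls lie above the 4 9G8 RNAi libraries, with means of 1384 and 264.2 CPM.

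Most genes of fat and sugar metabolism did not pass. None of 16 fatty acid synthesis genes changed (camera adjusted p = 0.439). Fatty acid synthase (CG3523, FASN1) was at 698.3 ± 365.4 and 832.6 ± 576.2 CPM (log2 fold change 0.25, SE 0.52), and the desaturase Desat1 at 2551 ± 1643 and 4065 ± 1065 CPM (0.67, SE 0.46). None of 16 genes of triglyceride synthesis and the lipid droplet coat changed (camera adjusted p = 0.126, and 0.0458 without control 2 and 0.0431 without 9G8 RNAi 1). Of 9 lipolysis genes mag rose and Lip3 fell, the latter from 7.61 ± 2.34 to 0.715 ± 0.243 CPM (-3.42, SE 0.44, adjusted p = 0.00171), and 4 passed when adjusted over the list alone. Of 22 fatty acid oxidation genes the peroxisomal acyl-CoA oxidase Acox57D-d rose (1.97, SE 0.45, adjusted p = 0.0361), a call kept in 1 of 8 fits that left a library out, without 9G8 RNAi 4 (adjusted p up to 0.111 in the others). In the glycogen and trehalose list (12 tested, camera adjusted p = 0.215, and 0.0447 without control 3) the alpha-glucosidase gene tobi fell from 12.3 ± 10.7 to 1.12 ± 0.14 CPM (-3.45, SE 0.73, adjusted p = 0.0247). The call of tobi ended without control 1 or 9G8 RNAi 1, 2 or 3 (adjusted p up to 0.106), with limma-voom (0.144) and with the replicate block (0.150). Inos, which makes inositol phosphate from glucose-6-phosphate, fell from 1310 ± 393.9 to 390.0 ± 206.2 CPM (-1.75, adjusted p = 0.0492), a call kept in 2 of 8 such fits, without control 4 or 9G8 RNAi 4 (adjusted p up to 0.213 in the others). With the replicate block the calls of Acox57D-d (0.209) and Inos (0.249) ended too, and with the gut covariate as well (0.173 and 0.0921). Inos did not pass with RLE factors (0.0928), TMM without the 20 most abundant genes (0.0774), no filter (0.0779) or a mean CPM of at least 1 (0.0570) either. No member changed among glycolysis and gluconeogenesis (16 tested), tricarboxylic acid cycle (15), nuclear-encoded oxidative phosphorylation (63), insulin, TOR and AKH signalling (23), adipokine (14) and one-carbon (14) genes. Their camera adjusted p-values were 0.396, 0.911, 0.0705, 0.0692, 0.911 and 0.250. Oxidative phosphorylation passed without control 4 (4.7e-04), 9G8 RNAi 3 (0.00408) or 9G8 RNAi 4 (0.00425), and insulin, TOR and AKH signalling without control 1 (0.0325), 9G8 RNAi 3 (0.0368) or 9G8 RNAi 4 (0.0114).

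The lists with the smallest camera p-values held immune and stress genes, and both were lower in 9G8 RNAi. Of 31 antimicrobial peptide and Bomanin genes, small secreted defence peptides made by the fat body, 5 fell, 0 rose and 26 did not pass. Adjusted over the list alone, 18 fell. Their median log2 fold change was -1.90 (camera adjusted p = 8.8e-15, and adjusted p = 0.697 with an estimated correlation). IM4 (Dso1, Daisho 1) fell from 1161 ± 566.0 to 133.8 ± 77.6 CPM (-3.12, SE 0.57, adjusted p = 0.0113) and the Bomanin CG15065 (BomS5) from 1193 ± 504.7 to 141.4 ± 111.7 CPM (-3.08, SE 0.65, adjusted p = 0.0244). Without control 2 or 9G8 RNAi 1 the call of BomS5 ended (adjusted p = 0.0722 and 0.0636), and with the replicate block those of IM4 (0.0665), BomS5 (0.0843), CG18067 (0.0623) and upd3 (0.0825) did. Without control 3 and 9G8 RNAi 2 together CG18067 (0.0645), TotA (0.0792), upd3 (0.0764) and PGRP-SD (0.177) were lost, and BomS5 (0.0563) and PGRP-SD (0.0805) with the gut covariate. CG18067 (Bombardier), known from Toll-dependent defence together with the Bomanins, fell from 2702 ± 1559 to 346.2 ± 157.4 CPM (-2.97, SE 0.50, adjusted p = 0.00691). It stands in the fixed list of spermatheca genes, of which 7 were tested and it alone passed. That list was lower by camera (adjusted p = 0.0173, and adjusted p = 0.752 with an estimated correlation), but not without control 4 (0.0698) or 9G8 RNAi 2 (0.0989). Of 12 Turandot and JAK-STAT genes, stress peptides and components and targets of a cytokine pathway, 4 fell, 0 rose and 12 had negative log2 fold changes. Adjusted over the list alone 10 fell (median -1.99, camera adjusted p = 3.7e-13, and adjusted p = 0.444 with an estimated correlation). Socs36E, the pathway's feedback inhibitor, fell from 43.3 ± 8.06 to 7.16 ± 1.67 CPM (-2.60, SE 0.32, adjusted p = 0.00161). Diedel fell from 7.38 ± 2.34 to 0.414 ± 0.227 CPM (-4.18, SE 0.51). TotA fell from 1611 ± 524.4 to 199.9 ± 182.4 CPM (-3.01, SE 0.59, adjusted p = 0.0164), and the cytokine gene upd3 from 1.88 ± 1.29 to 0.256 ± 0.072 CPM (-2.88, adjusted p = 0.0187). The calls of TotA and upd3 ended without 9G8 RNAi 1, 2 or 3 (adjusted p up to 0.0634 and 0.0772). Of 18 peptidoglycan recognition and humoral immunity genes only PGRP-SD passed (-3.12, adjusted p = 0.0444), in 2 of 8 fits that left a library out, without 9G8 RNAi 3 or control 4 (adjusted p up to 0.106 in the others). In that list 6 fell when adjusted over the list alone (camera adjusted p = 0.00132, and 0.635 with an estimated correlation).

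Markers of hemocytes, the blood cells that adhere to the fat body, moved the same way. Of 13 hemocyte markers 3 fell, 0 rose and 13 had negative log2 fold changes, and 7 fell when adjusted over the list alone (median -1.32, camera adjusted p = 1.6e-07, and 0.635 with an estimated correlation). He (-1.96, adjusted p = 0.0364), NimB4 (-1.58, 0.0398) and Pxn (-1.54, 0.0465) passed, each in 2 of 8 fits that left a library out. The hemocyte score was 4.39 ± 0.49 in controls and 3.23 ± 0.31 in 9G8 RNAi (exact two-sided permutation p = 0.0286, the smallest it can give, and 0.321 adjusted over 15 scores). The calls were lost for He without control 1, 2 or 4 or 9G8 RNAi 1, 2 or 3, for NimB4 without control 1, 2 or 3 or 9G8 RNAi 1, 2 or 3, and for Pxn without control 1, 2 or 4 or 9G8 RNAi 1, 3 or 4 (adjusted p up to 0.154, 0.171 and 0.196). With the replicate block none of these 3 passed (0.168, 0.178 and 0.213), nor with TMM without the 20 most abundant genes (0.0516, 0.0586 and 0.0659) or no filter (0.0532, 0.0532 and 0.0559).

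**Figure D3:**
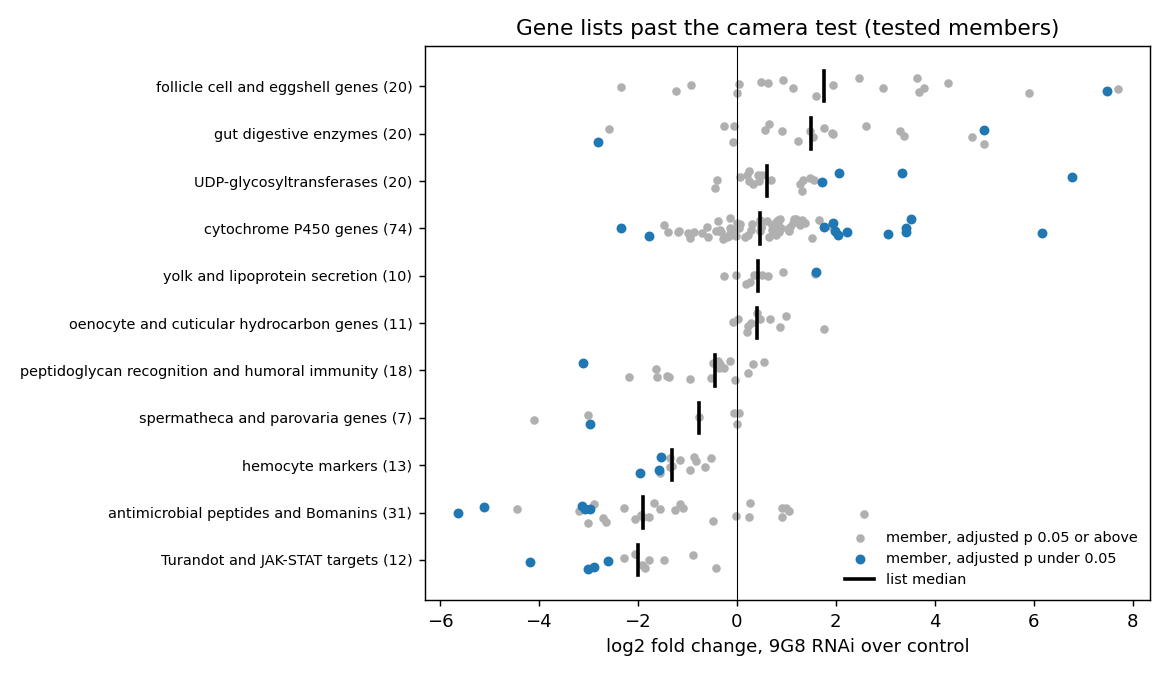
Log2 fold change (9G8 RNAi over control) of the tested members of the 11 lists that passed camera at the preset correlation; the number tested is in parentheses. Blue points are members that passed edgeR's test, grey points members that did not, and black bars list medians, from -1.99 for Turandot and JAK-STAT genes to 1.77 for eggshell genes.

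Genes for detoxification were among the rises. Of 74 cytochrome P450 genes 10 rose, 2 fell and 62 did not pass. Adjusted over the list alone 21 rose and 6 fell (median 0.47, camera adjusted p = 5.8e-05, and 0.865 with an estimated correlation). Cyp12c1 rose from 11.1 ± 3.06 to 127.5 ± 61.0 CPM (3.52, SE 0.43, adjusted p = 0.00161) and Cyp6w1 from 3.03 ± 0.87 to 32.2 ± 17.3 CPM (3.41, SE 0.46), while Cyp28d1 fell from 15.2 ± 2.76 to 2.98 ± 0.81 CPM (-2.35, SE 0.35, adjusted p = 0.00359). Of 20 UDP-glycosyltransferases, which conjugate sugars to xenobiotics, 4 rose and 0 fell, the same counts when adjusted over the list alone (median 0.60, camera adjusted p = 3.2e-06, and 0.697 with an estimated correlation). Beside Ugt37A3 these were its neighbour CG5724 (Ugt37A2, 3.34), CG15661 (Ugt49C1, 2.07) and CG4302 (Ugt49B1, 1.72). The P450 list's camera adjusted p was 0.161 with the gut score as a covariate, and CG15661, CG5724 and CG4302 no longer passed in that fit (0.0778, 0.0504 and 0.107). CG5724 also ended without 9G8 RNAi 2 (0.0562), and CG4302 without control 3 (0.0507) or 9G8 RNAi 3 (0.0616). Of 33 glutathione transferase and antioxidant genes 2 rose (GstE1 and GstE7) and 2 fell (GstD2 and GstD5), with 4 and 2 when adjusted over the list alone (camera adjusted p = 0.647). GstE7 (1.70) lost its call without control 1, 2 or 4 or 9G8 RNAi 3 (adjusted p up to 0.0784). GstD2 (-3.34) and GstD5 (-2.43), of a cluster of similar genes, passed in 4 and 2 of the 8 fits. GstD2 lost its call without control 1 or 4 or 9G8 RNAi 2 or 3, and GstD5 without control 1, 2 or 4 or 9G8 RNAi 1, 2 or 4 (adjusted p up to 0.0817 and 0.118). With the replicate block CG4302 (0.0937), GstE7 (0.0665) and GstD5 (0.107) were lost. Without control 3 and 9G8 RNAi 2 together GstD2 (0.0771), GstD5 (0.158), CG15661 (0.0965), CG5724 (0.0623) and CG4302 (0.0774) were.

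Among 11 heat shock genes 3 rose, 1 fell and 7 did not pass, with 3 and 3 when adjusted over the list alone (camera adjusted p = 0.439). The risers were Hsp70 copies with near-identical sequence, whose reads cannot be assigned with certainty: Hsp70Bb, with 177 counts over the controls and 19821 over 9G8 RNAi, Hsp70Ab with 35 and 262, and Hsp70Bbb with 3 and 72. Hsp23, a small heat shock protein, fell from 84.4 ± 37.9 to 6.26 ± 3.23 CPM (-3.76, SE 0.53, adjusted p = 0.00275). Hsp70Ab lost its call without control 2 or 3 or 9G8 RNAi 2 or 3 (adjusted p up to 0.0625) and with the replicate block (0.0502), and with the gut covariate Hsp70Ab (0.0843) and Hsp70Bbb (0.124) did, as they did without control 3 and 9G8 RNAi 2 together (0.144 and 0.0946). None of 18 unfolded protein response and ER chaperone genes changed (camera adjusted p = 0.673), nor did 32 proteasome genes (0.673), 72 mitochondrial ribosomal protein genes (0.911), 13 mitochondrially encoded genes (0.647) or 8 circadian clock genes (0.837). Of 85 cytosolic ribosomal protein genes (0.273) RpL37b alone passed, a duplicate of RpL37a (10.1 ± 7.32 CPM in 9G8 RNAi, 0.896 ± 0.238 in controls, log2 fold change 3.50), and similar sequence leaves its reads uncertain. Its call ended with the replicate block (adjusted p = 0.0526). Without 9G8 RNAi 2 the mitochondrially encoded (0.0018), mitochondrial ribosomal (7.7e-04) and cytosolic ribosomal (3.7e-07) lists passed camera, and the last also without control 2 (0.0377).

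Secreted fat body products moved in both directions. Yolk protein 2 (Yp2) rose from 1651 ± 561.0 to 5013 ± 1646 CPM (log2 fold change 1.60, SE 0.40, adjusted p = 0.0490); its call was kept in 1 of 8 fits that left a library out, without 9G8 RNAi 4, with adjusted p up to 0.153. It did not pass with the replicate block (0.309), the gut covariate (0.316), RLE factors (0.0679), no filter (0.0584) or a mean CPM of at least 1 (0.0520). Of 10 yolk and lipoprotein genes 1 rose, 0 fell and 9 did not pass, the same when adjusted over the list alone (median 0.43, camera adjusted p = 0.0354, and 0.865 with an estimated correlation). That list no longer passed without control 3 (0.188), control 4 (0.0698) or 9G8 RNAi 2 (0.172), or with the gut covariate (0.558). Yolk proteins are also made by ovarian follicle cells, and the eggshell score was 0.75 ± 2.67 in controls and 2.95 ± 2.63 in 9G8 RNAi. In neither genotype did the library with the highest eggshell score hold the most Yp2. In 9G8 RNAi 1 (score 6.53) Yp2 was at 3852 CPM and in 9G8 RNAi 2 (0.21) at 7345 CPM. In control 4 (4.69) it was at 1517 CPM and in control 2 (-0.02) at 2355 CPM. Odorant-binding protein 99b (Obp99b), secreted by the fat body, fell from 1334 ± 246.8 to 65.2 ± 80.7 CPM (-4.36, SE 0.75, adjusted p = 0.00723), a call lost without control 3 and 9G8 RNAi 2 together (0.0764). With a library left out its log2 fold change ranged from -5.74, without 9G8 RNAi 4, to -3.96. The storage protein gene Lsp2 fell from 57.4 ± 33.9 to 9.94 ± 5.31 CPM (-2.53, adjusted p = 0.0224), a call lost without control 1 or 4 or 9G8 RNAi 1, 2 or 3 (adjusted p up to 0.0810) and without control 3 and 9G8 RNAi 2 together (0.0993). Of 15 adult fat body markers 1 rose, 2 fell and 12 did not pass, with 4 and 4 when adjusted over the list alone. Their median was 0.18, their mean -0.28 and camera's direction down (adjusted p = 0.841).

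Markers of gut and of ovary varied between libraries of a genotype. Of 20 gut digestive enzymes deltaTry rose, LysX fell and 18 did not pass (median 1.51, camera adjusted p = 9.1e-06, and 0.865 with an estimated correlation), with 6 higher and 1 lower when adjusted over the list alone. The gut score was 5.41 ± 2.36 in controls, with control 3 at 2.03, and 7.55 ± 0.49 in 9G8 RNAi (exact two-sided permutation p = 0.0857, adjusted 0.321). LysX, a lysozyme, fell from 16.9 ± 1.00 to 2.42 ± 1.27 CPM (-2.81, SE 0.40, adjusted p = 0.00289), while deltaTry had 8 counts over the controls and 293 over 9G8 RNAi and lost its call without control 2 (0.0659) or 9G8 RNAi 2 (0.0670), without control 3 and 9G8 RNAi 2 together (0.148) and with the gut covariate (0.0590). Of 20 follicle cell and eggshell genes Vm26Ac passed (7.48, adjusted p = 0.0487), 3 passed when adjusted over the list alone, and the groups of Vm26Ac overlapped (median of the list 1.77, camera adjusted p = 0.00169, and 0.924 with an estimated correlation). Without 9G8 RNAi 1, whose eggshell score was 6.53, the list no longer passed (0.218). Vm26Ac passed in 2 of 8 such fits, without control 4 or 9G8 RNAi 4 (adjusted p up to 0.145 in the others), and not with limma-voom (0.213), the replicate block (0.597) or the gut covariate (0.166). None of 20 germline markers changed (camera adjusted p = 0.0543), and that list passed without control 3 (6.35e-04), control 4 (8e-04), 9G8 RNAi 3 (0.0363) or 9G8 RNAi 4 (0.0117). The germline list's correlation estimated over all libraries was 0.809, against the preset 0.01, and camera with that value gave adjusted p = 0.932. None of 11 oenocyte genes changed, although the list passed camera upwards (median 0.40, adjusted p = 0.0347, and 0.865 with an estimated correlation), a call lost without control 3 (0.0878), control 4 (0.265), 9G8 RNAi 2 (0.0989) or 9G8 RNAi 4 (0.127), or with the gut covariate (0.320). Of 21 muscle markers TpnC73F fell (-1.43, adjusted p = 0.0387; list 0.841), a call kept in 2 of 8 fits, without control 3 or 9G8 RNAi 4 (adjusted p up to 0.187), and lost with the replicate block (0.258), TMM without the 20 most abundant genes (0.0528) and no filter (0.0595). Malpighian tubule (13 tested, 0.911), neuronal (11, 0.994) and heart and pericardial (7, 0.673) markers held no changed gene. In the list of male genes 2 were tested, and neither changed.

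**Figure D4:**
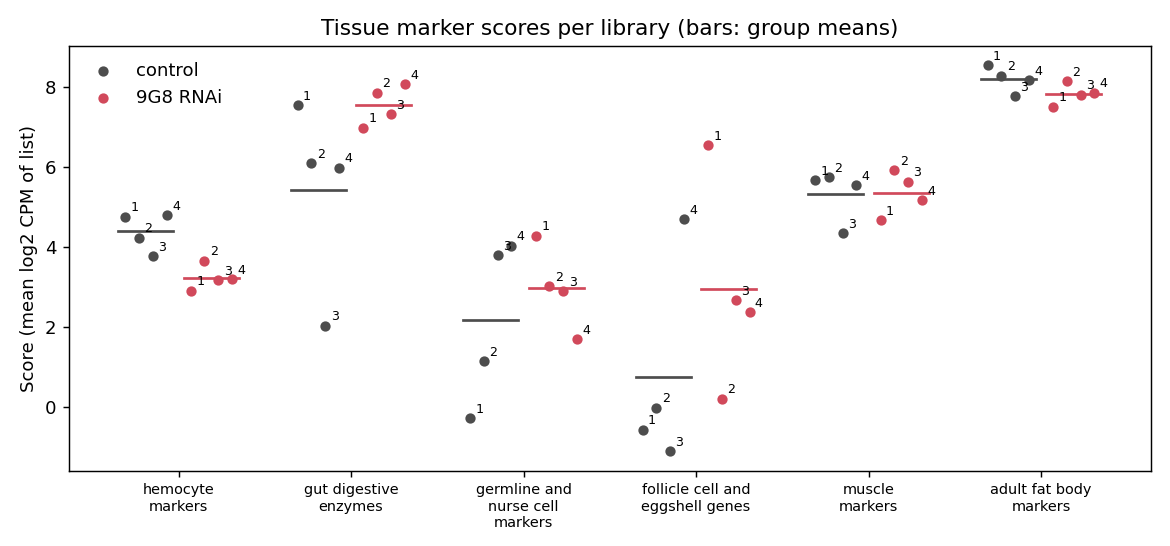
Tissue marker scores (mean log2 CPM of a list) in each library. Points are libraries with their replicate number, n = 4 per genotype, and bars are group means; the hemocyte score averages 4.39 in controls and 3.23 in 9G8 RNAi, and control 3 stands at 2.03 on the gut score.

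The eye colour gene white (w), which marks many transgenes, was at 107.5 ± 47.2 CPM in controls and 275.7 ± 68.6 CPM in 9G8 RNAi. The 4 values of 9G8 RNAi lay above the 4 controls, but w did not pass (log2 fold change 1.36, SE 0.40, adjusted p = 0.106). With the germline score as a covariate it did (1.58, adjusted p = 0.0304). Counted gene by gene, the share of changed genes differed between chromosome arms. On 2R 93 of 2037 tested genes changed, 4.57% against 2.86% elsewhere (Fisher's exact test, odds ratio 1.63, adjusted p = 5.2e-04 over 6 arms). On X 29 of 1661 changed, 1.75% against 3.51% elsewhere (odds ratio 0.489, adjusted p = 5.2e-04). These tests take neighbouring genes as independent, and with changed neighbours within 20 kb counted as 1 neither arm passed (adjusted p = 0.138 for 2R and 0.0588 for X). The shares on 2L, 3L, 3R and 4 did not differ from elsewhere (adjusted p = 0.942).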

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

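The tests of x16, of dilution, hemocytes and strain for the immune genes, and of Hsp70Bb were chosen only after the results were seen. The test of library scaling and the splits of the samples were planned.

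In 12 of 186 groups of 4 libraries tested, a library stood far from the other 3, where chance gives about 1 in 20. The gap is given as a share of the group's range. Control 3 had a low muscle score (4.34, others at least 5.54, gap 0.85), and was low for TpnC73F (log2 CPM 3.42, others at least 4.28, gap 0.88) and GstD5 (2.25, others 3.09 to 3.24, gap 0.85). Control 4 was low for Rootletin (5.33, others 7.50 to 7.61, gap 0.95), and control 2 was high for CG18067 (12.3, others up to 10.98, gap 0.90). In 9G8 RNAi 2, Idh was high (8.42, others 7.55 to 7.66, gap 0.87) and Nmdmc low (3.38, others 4.08 to 4.22, gap 0.83). In 9G8 RNAi 1 thetaTry was low (2.497, others at least 6.28, gap 0.84), and in 9G8 RNAi 3 Ser12 was low at 0 counts (-4.02, others at least -3.25, gap 0.87). Near-empty genes gave a gap of 1.00 in controls, where a single library held counts: control 4 for Hsp70Bbb, control 3 for Cyp12d1-d and control 1 for deltaTry.

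Other ways of splitting the 8 libraries into 4 and 4 were run for each count. Of the 35 splits, 2, that by genotype included, gave as many changed genes as the genotypes (316), as many higher (98), as many lower (218) and as many changed by at least 2-fold (316). By this count chance cannot be excluded for these numbers. The highest other counts were 795 genes, 625 in one direction and 752 by at least 2-fold. They came from exchanging control 4 with 9G8 RNAi 4. That split called more genes than the genotypes, most of them in one direction, and points to a structure of the samples. It shared 13 calls with the comparison of genotypes. For lists, 23 of the 35 splits, the real one included, gave at least 11 calls by camera (highest other 24), so chance cannot be excluded there either.

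The x16 transcript was not called lower in 9G8 RNAi. A library swapped between the genotypes is argued against by w, for which 0 libraries lay within the other group's range. Over the 8 libraries x16 went with the germline score (Pearson r = 0.631, permutation p = 0.0946; Spearman rho = 0.619, permutation p = 0.114), and r was 0.728 without the 2 libraries farthest from the median score, controls 1 and 2. With the germline score as a covariate the group coefficient was -1.02 (SE 0.58, exact permutation p = 0.229). RNA from ovarian germline may thus add x16 transcripts and mask a knockdown, but with 8 libraries neither can be told apart from no knockdown.

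The pooled Turandot, antimicrobial and Bomanin genes (43 tested, 36 with a negative log2 fold change) had a median of -1.91. Library scaling is argued against, since without scaling factors the median was -1.909. Dilution by other tissues is argued against by the yolk and lipoprotein genes, at a median of 0.43 with an SD of 0.63, although follicle cells also make yolk proteins. Per library the pooled mean minus the yolk mean differed by -2.76 (SE 0.82, exact permutation p = 0.0286). The immune lists were pooled after their fall was seen, so this p mostly restates that fall. A lower share of hemocytes stays open: the median of the pooled lists minus that of the hemocyte markers was -0.597 (95% bootstrap interval over genes -1.39 to -0.21, which met the bound set against this explanation), but genes are not independent, and per library the difference of -1.06 (SE 0.77, exact permutation p = 0.257) lay within the spread. Strain background or rearing that goes with genotype stays open too and cannot be told apart from the hairpin: 4 of 4 controls lay above every 9G8 RNAi library in the lists' mean. The groups nearly touched there, with control 3 at a mean log2 CPM of 5.775 and 9G8 RNAi 3 at 5.709. Controls 1, 2 and 4 were at 6.481, 7.250 and 6.581, and 9G8 RNAi 1, 2 and 4 at 4.119, 2.787 and 4.602.

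Hsp70Bb was higher in 4 of 4 9G8 RNAi libraries, with at least 2749 counts against at most 131 in controls. A general heat shock response is argued against by the other 8 heat shock genes tested, Hsp70 copies left out, at a median of -0.33. The standard error of their mean over the 8 genes, which takes genes as independent, was 0.50. Per library their mean differed from a rise of 1 by -1.90 (SE 0.47, exact permutation p = 0.0286). Other Hsp70 copies together held 2.02% of the Hsp70Bb counts in 9G8 RNAi and 32.8% in controls. The smaller share does not mean that these copies fell. Hsp70Ab, with 35 counts over the controls and 262 over 9G8 RNAi, and Hsp70Bbb, with 3 and 72, were called higher. Hsp70Aa, Hsp70Ba and Hsp70Bc were too scarce to be tested. A candidate explanation is Hsp70 sequence in the vector of the hairpin transgene, since such vectors often carry an Hsp70 promoter, but the vector is not named in the labels and the files hold no positions of reads. A true rise of this copy stays open.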

How the results depend on the processing

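Of the alternatives, RLE factors, TMM without the 20 most abundant genes, limma-voom and a mean CPM of at least 1 left each count of changed genes within 1.5 times its value, and no gene called in the comparison of genotypes changed sign in any setting. TMM without the 20 most abundant genes moved the median log2 fold change of all genes to 0.105, and no filter to 0.111. DESeq2 gave 557 changed genes (200 higher, 357 lower, all by at least 2-fold) and kept 313 of the 316. No filter gave 149 higher. With a library left out, changed genes ranged from 162 to 504 (the same for at least 2-fold), higher from 51 to 124 and lower from 105 to 380. Settings added after the data were seen gave 484 changed and 195 higher (germline covariate), 137 lower (eggshell covariate), 32 higher (gut covariate), 126 lower (without control 4 and 9G8 RNAi 1), and 96 changed, 28 higher and 68 lower (without control 3 and 9G8 RNAi 2, where fewer samples lower the power). Camera with an estimated correlation called 0 lists (smallest adjusted p 0.444), fry directional 1 and fry mixed 14, against 11. The cause was not tested for the other settings.

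The replicate numbers did not pair the samples: correlations of deviations for the same number were -0.572, -0.250, -0.018 and -0.593. With the replicate block, 141 genes changed (37 higher, 104 lower), 140 of them among the 316, and 22 of the 61 named genes that had passed no longer did.

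The results whose direction turned had not passed, apart from the eggshell list. The log2 fold change of x16 was 0.638 with the gut covariate and 0.362 without control 3 and 9G8 RNAi 2, and ranged from -1.201 to 0.095 with a library left out. Men was at -0.020 with the gut covariate and -0.261 without control 3 and 9G8 RNAi 2 (range with a library left out -0.213 to 0.592). Men-b was at 0.030 (TMM without abundant genes), 0.059 (limma-voom), 0.016 (no filter), 0.095 (replicate block) and 0.472 (without control 4 and 9G8 RNAi 1), with a range of -0.378 to 0.590. CG3523 was at -0.306 (gut covariate) and -0.593 (without control 3 and 9G8 RNAi 2), with a range of -0.370 to 0.601, and U2af50 at -0.009 (without control 4 and 9G8 RNAi 1), with a range of -0.010 to 0.327. Muscle markers turned downwards at adjusted p = 0.0447 (gut covariate) and 0.0415 (without control 3 and 9G8 RNAi 2), and eggshell genes at 0.992 (eggshell covariate, which removes their own mean). In simulated data of the same depth and spread 2.35% of 2-fold changes were called, so smaller changes were mostly out of reach.

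Of the 61 named genes that had passed, RLE factors ended the calls of Zw, Yp2, PGRP-SD, NimB4, Pxn, Rootletin and Inos (adjusted p 0.0522 to 0.0928). TMM without abundant genes ended those of TpnC73F, He, NimB4, Pxn and Inos (0.0516 to 0.0774), no filter those of Yp2, TpnC73F, He, NimB4, Pxn and Inos (0.0532 to 0.0779), and a mean CPM of at least 1 those of Yp2, PGRP-SD, Vm26Ac, Pxn, Rootletin and Inos (0.0514 to 0.0576). Limma-voom ended tobi and Vm26Ac, DESeq2 0. The eggshell covariate ended Zw, Acox57D-d, Yp2, PGRP-SD, GstE7, GstD5, TpnC73F, Vm26Ac, He, NimB4, Pxn and Inos (0.0619 to 0.217), and the germline covariate Pxn (0.0504). Without control 4 and 9G8 RNAi 1 the calls of Acox57D-d, tobi, Yp2, Lsp2, upd3, GstE7, GstD5, CG4302, TpnC73F, He, NimB4, Pxn, Rootletin and Inos ended (0.0626 to 0.261). Without control 3 and 9G8 RNAi 2 the 29 were CG4563, thetaTry, CG17192, lambdaTry, CR34262, Zw, Acox57D-d, Yp2, Obp99b, Lsp2, PGRP-SD, TotA, upd3, Hsp70Bbb, Hsp70Ab, GstD2, GstD5, CG15661, CG5724, CG4302, Vm26Ac, He, NimB4, deltaTry, CG18067, glob1, Arc1, Rootletin and Inos (0.0623 to 0.210). With the gut covariate the 19 were mag, lambdaTry, Acox57D-d, Yp2, BomS5, PGRP-SD, Hsp70Bbb, Hsp70Ab, GstD5, CG15661, CG5724, CG4302, Vm26Ac, NimB4, deltaTry, glob1, Arc1, Rootletin and Inos (0.0504 to 0.316). With the replicate block the 22 were Zw, Acox57D-d, tobi, RpL37b, Yp2, IM4, BomS5, upd3, Hsp70Ab, GstE7, GstD5, CG4302, TpnC73F, Vm26Ac, He, NimB4, Pxn, CG18067, glob1, Arc1, Rootletin and Inos (0.0502 to 0.597). Of the lists, yolk and lipoprotein (0.535), oenocyte (0.271) and spermatheca (0.0681) genes no longer passed without control 3 and 9G8 RNAi 2, and oenocyte (0.0657) and spermatheca (0.219) genes without control 4 and 9G8 RNAi 1.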

Other observations

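The unadjusted test of the 2R excess and those of both families were planned before their values were computed; the families and the genes named here were chosen after the values of single genes were seen, and the families' fits under other scalings or with a library left out, as well as the adjustment over the arms, were added after that. Genes annotated as ecdysteroid kinase-like, a family named for enzymes that phosphorylate steroid hormones, held 3 of the 10 largest rises named for the comparison. Of 41 tested members 7 rose and 0 fell, and 32 had a positive log2 fold change. The family's median was 0.58 (camera p = 1.5e-10, and p = 0.0431 with an estimated correlation), and 0.58 without the 3 genes that prompted the test (camera p = 1.4e-07 at the preset correlation). The p with an estimated correlation includes these 3 genes and was not computed without them. The median stayed positive under RLE factors (0.63), TMM without the 20 most abundant genes (0.71) and no scaling (0.89), and was 0.43 to 0.92 with a library left out. CG32195 rose from 18.9 ± 8.41 to 77.8 ± 16.7 CPM (log2 fold change 2.04, adjusted p = 0.0119) and CG6834 (3.27, SE 0.56, adjusted p = 0.00712) rose too, both with each library left out in turn. CG13813 lost its call without control 2 (adjusted p = 0.0525) or 9G8 RNAi 2 (0.0505), and CG16898 without control 2, 3 or 4 or 9G8 RNAi 2 or 3 (0.104, 0.0928, 0.0865, 0.0706 and 0.0658). Several lie side by side on 3R, where similar sequence can split reads.

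Odorant-binding protein genes went both ways. Of 17 tested 3 fell and 1 rose, with a median of -0.71 (camera p = 9.4e-05, and p = 0.220 with an estimated correlation) and of -0.50 without Obp99b. Obp99d (-4.62, adjusted p = 0.00245) and Obp57c (-1.70, adjusted p = 0.0490) fell beside Obp99b, while Obp99a, from the same region of 3R as Obp99b, rose from 27.2 ± 22.6 to 159.8 ± 94.2 CPM (2.55, adjusted p = 0.0341). Left out one at a time, the libraries ended the call of Obp99a in 6 of 8 fits, without control 1, 2 or 4 or 9G8 RNAi 1, 2 or 3 (adjusted p = 0.0984, 0.107, 0.0865, 0.0548, 0.0772 and 0.0992). The call of Obp57c was kept only without 9G8 RNAi 4 (adjusted p = 0.0628 to 0.202 in the others, without control 1 to 4 or 9G8 RNAi 1 to 3). The family's median stayed negative under RLE factors (-0.69), TMM without the 20 most abundant genes (-0.60) and no scaling (-0.60).

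Within the antimicrobial list, members differed in sign. Peptides known as targets of the Imd pathway, Dpt (2.56, SE 1.15), DptB (1.06, SE 1.01) and AttA (0.92, SE 1.10), had positive log2 fold changes and did not pass, while AttC (-1.90, SE 0.87) and CecB (-3.01, SE 1.11) were negative and did not pass either. Bomanins and Daisho peptides, known as Toll targets, were negative in each tested member, from -0.49 for CG18107 (BomS4) to -3.14 for IM23 (BomBc1), and 3 of them passed. The difference between these subsets was not tested.

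Among the changed genes 15 clusters held 3 or more with gaps of at most 20 kb, such as the trypsins, the Cpr49A cuticle genes and 4 genes around CG30090 (Erasp) on 2R. Clusters of neighbouring genes as the cause of the 2R excess were tested by counting neighbours within 20 kb as 1. On 2R the odds ratio was then 1.36, against 1.63 before, with a Fisher's exact p of 0.0459, or 0.138 adjusted over the 6 arms. The unadjusted p met the bound set beforehand for an excess that outlasts clustering, but that bound was wrong: the 2R call itself is adjusted over the 6 arms, and on that scale it ended. Clusters as the cause therefore stay open, and whether neighbours changed together more than chance gives was not tested. On X the odds ratio was 0.592 (Fisher's exact p = 0.00980, adjusted p = 0.0588).

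In the split that exchanges control 4 with 9G8 RNAi 4, the genes with the smallest adjusted p included some known for ribosome production in the nucleolus, chosen after their values were seen: RpI135 (2.15), nop5 (2.16), Nnp-1 (2.33), Surf6 (2.26) and ppan (2.64), higher in control 4 and 9G8 RNAi 1 to 3. No list of such genes was fixed or tested. In that split 4 of 20 eggshell genes were higher on the same side, with a list median of 4.13. Medians on that side were 1.23 for germline markers, -1.58 for Turandot and JAK-STAT genes and -1.08 for antimicrobial and Bomanin genes. Neither of these immune lists held a called gene there. Since 9G8 RNAi 1 to 3 lie on that side, differences between the genotypes can enter these medians.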
